A study of Mus musculus with 15 samples.

How the data were processed

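RNA of mouse skin was measured in 15 libraries of 4 groups. The deposited table holds estimated counts per gene for these libraries under versioned Ensembl mouse gene identifiers, per the file headers, and the values carry fractions and no scaling to library size. Per the submitters' processing notes the tools were FastQC, Trim Galore, HISAT2 and featureCounts, without versions, with genome build GRCm39. No header or label says which of these tools wrote the table, and no label states whether the libraries were stranded.

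Columns of vehicle libraries name their group and number. Columns of the treated groups carry short names, with the numbers 1, 2, 4 and 5 for Wnt-C59 and 2, 3, 4 and 5 for the combination. The first were matched by their name. The second carry a 2-letter code that no label spells out, and they were matched to the combination because no other group of the series was left. Treated libraries are named here by these column numbers, which are not the numbers in the sample titles.

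Of the 56059 genes in the table, 51276 (91.5%) were matched to a symbol by their identifier, and no gene was named otherwise. The annotation at hand was GENCODE release M21 for build GRCm38, which differs from the build of the study, so it was used only for symbols, GC content and the length of the longest transcript, and no coordinates are given.

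The estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. The design had assumed whole counts. Libraries were scaled by TMM, genes were kept by filterByExpr with the 4 groups (18651 genes tested), and a quasi-likelihood model with robust estimation was fitted to all 15 libraries with the group as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. CPM values are counts per M (mega) of the TMM-scaled library size, given as group means with SD. The 4 main comparisons were allogeneic against syngeneic, each treated group against allogeneic, and the combination against Wnt-C59. Both treated groups were also compared with syngeneic skin as secondary comparisons.

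Genes to be named were set by a rule. It took the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. Immunoglobulin and T cell receptor segments, genes with only a predicted or clone name, pseudogenes of ribosomal proteins and the sex-linked check genes were left out of that part. The rule added up to 4 called members of each gene list in order of adjusted p, or the 1 or 2 with the smallest adjusted p where none was called, and 10 genes in every comparison (Porcn, Rock1, Rock2, Axin2, Lef1, Col1a1, Col3a1, Acta2, Cd3e and Cxcl9). The text names only part of the genes that the rule took, and one of them is not reported at all. Any other gene is marked as chosen after its values were seen.

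A total of 35 gene lists were written from textbook knowledge of skin, graft-versus-host disease, fibrosis, Wnt signalling and ROCK signalling, and 489 of their 490 members had a symbol in the table. They were tested with camera of limma 3.58.1 on log-CPM values (prior count 2) with a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry. Counts of members up or down adjusted over the list alone are printed where they differ from those over all genes. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. Median, mean and camera direction of a printed list differed in sign for the aryl hydrocarbon receptor and NRF2 targets (allogeneic against syngeneic), the TGF-beta list (each treated group against allogeneic) the collagens (Wnt-C59 against syngeneic) and the muscle markers (combination against syngeneic), none of them called by camera. Some genes stand in 2 lists, such as Cxcl9 and Ccl5. The score of a list in a library is the mean log2 CPM of its members.

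A fold against a group with no counts is a lower bound, computed at 3 counts per library of that group. With 1 to 3 counts in the lower group the ratio is given with its 95% counting interval. Such bounds and intervals cover counting error only, not the spread between animals. Genes with near-identical copies, such as the Krtap, Stfa, Chil, Sprr2, Gbp and Serpina3 families and the Pgam1 pseudogene, are uncertain, since the table does not say how reads that fit several genes were shared. The same holds for overlapping and antisense genes, since no label states the strand setting.

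On simulated counts drawn from the real means and library sizes, 200 genes were changed by known folds. The same steps recovered 24.6% of the 2-fold and 85.5% of the 4-fold changes for allogeneic against syngeneic (18156 genes run). They recovered 34.2% and 89.3% for Wnt-C59 against allogeneic (18175 genes), and 18.3% and 89.2% for the combination against allogeneic (18120 genes). For the combination against Wnt-C59 they recovered 27.5% and 97.4% (18114 genes), with 4 false calls among 99.

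The comparisons, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. These alternatives were DESeq2 1.42.0, limma-voom, the size factors of DESeq2 and TMMwsp in edgeR, no filter on low counts, a filter at 5 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block, the skeletal muscle score or the adipocyte score as a covariate, a 2-fold minimum and leaving out each library in turn. Alternatives added after seeing the data were the removal of each library's trend over GC content and transcript length (a natural spline with 5 degrees of freedom, used as an offset), the fit without the combination libraries numbered 4 and 5, the hair follicle score as a covariate and a block on the column numbers of the treated libraries. GC content and length were known for 97.7% of the tested genes.

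For the reversal of changes, log2 fold changes of allogeneic against syngeneic skin were set against those of each treated group against allogeneic skin across genes, beside 100 simulations of unchanged groups that shared the same allogeneic libraries (20 for counts of calls). Each treated library was also placed on the line from the syngeneic mean (0) to the allogeneic mean (1) by its log-CPM values over the genes called between these groups, and each vehicle library was placed so after it was left out of both steps.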

Results

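Skin was sequenced in a mouse model of sclerodermatous chronic graft-versus-host disease, in which donor immune cells attack the skin of the recipient after a bone marrow transplant. The 4 groups were syngeneic recipients given vehicle, 0.4% methylcellulose (n = 4), and allogeneic recipients given vehicle (n = 3), Wnt-C59 at 5 mg/kg (n = 4), or Wnt-C59 at 5 mg/kg with belumosudil at 150 mg/kg (n = 4). Oral dosing was daily between day 21 and day 49 after the transplant. Wnt-C59 inhibits porcupine, the enzyme that attaches the lipid Wnt ligands need for secretion, and belumosudil inhibits the kinase ROCK2. The last group is called the combination here, and its libraries were matched to it by elimination.

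Total estimated counts ran from 16.26 to 20.39 M in the 7 vehicle libraries and from 18.99 to 28.78 M in the 8 treated libraries, and 22110 to 24283 genes were detected per library. The first principal component held 38.4% of the variance and the second 30.5%. Libraries of one group correlated with each other at r = 0.891 to 0.979 across genes, which are not independent replicates. Vehicle and treated libraries also differed in ways that no group label names. Between 31.07% and 34.39% of the non-zero values were not whole numbers in vehicle libraries, against 44.76% to 60.62% in treated libraries. Malat1, a nuclear RNA chosen after its values were seen, lay at 1070 to 3500 CPM in vehicle and at 65 to 136 CPM in treated libraries. Across genes, the log2 fold changes of Wnt-C59 against allogeneic skin followed GC content with a Spearman rho of 0.504, those of the combination with 0.541, and those of allogeneic against syngeneic skin with −0.10. No label gives a batch, and treatment and any batch that follows the same split cannot be told apart.

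**Figure D1:**
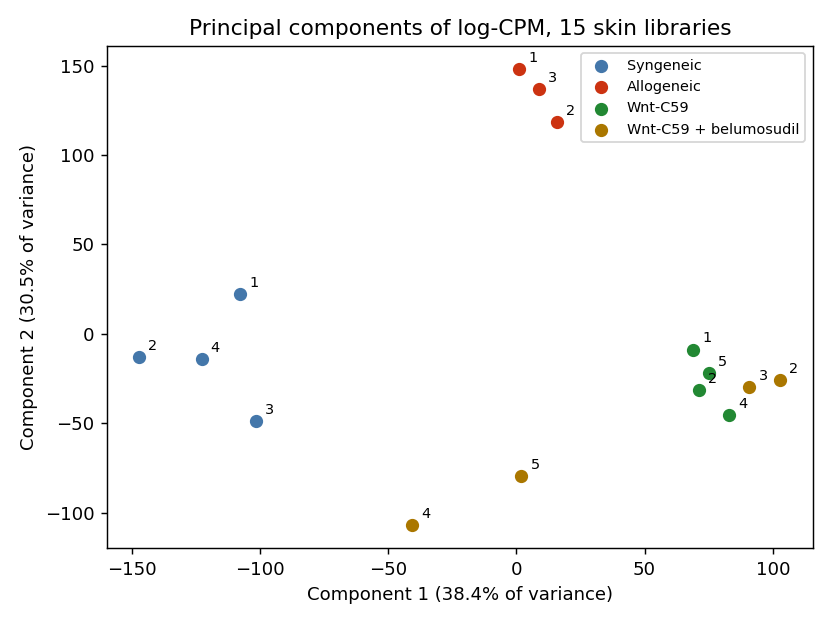
Principal components of log-CPM values of the 15 libraries, one point per library with its number, colored by group, with the share of variance on each axis (38.4% and 30.5%). Of the combination libraries, those numbered 4 and 5 lie apart from those numbered 2 and 3.

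Allogeneic skin was compared with syngeneic skin, both under vehicle, to see what the foreign graft changed. Genes of inflammation rose and genes of hair follicles and sebaceous glands fell. Cxcl9 (ENSMUSG00000029417), a chemokine that interferon-gamma induces and that attracts T cells, rose from 4.51 ± 2.55 CPM (SD, n = 4) to 433 ± 215 CPM (SD, n = 3; log2 fold change 6.58, SE 0.82, adjusted p = 0.00013). Cd3e (ENSMUSG00000032093), a chain of the T cell receptor complex, rose from 1.25 ± 0.42 to 10.6 ± 2.29 CPM (log2 fold change 3.09, SE 0.35, adjusted p = 3.5e-05). Far2, an enzyme that makes fatty alcohols for sebum, fell from 152 ± 27.4 to 2.62 ± 0.531 CPM (log2 fold change −5.85, SE 0.31, adjusted p = 8.4e-08). Of the 20 interferon-gamma response genes, 20 rose (camera adjusted p = 3.7e-14, adjusted p = 0.22 with an estimated correlation). Of the 23 hair follicle genes, 20 fell and 3 did not pass (0 up and 23 down adjusted over the list alone, camera adjusted p = 9.3e-11, adjusted p = 0.24 with an estimated correlation). Of the 10 sebaceous gland markers, 7 fell and 3 did not pass (camera adjusted p = 7.7e-09, adjusted p = 0.056 with an estimated correlation). In the edgeR test 5556 of 18651 genes (29.8%) changed, 2732 up and 2824 down, and 3511 of them by at least 2-fold. With the adipocyte score as a covariate 3157 genes were called.

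The immune lists of allogeneic skin moved mostly one way. Among the 17 T cell markers, 15 rose and 2 did not pass (camera adjusted p = 3.3e-12, adjusted p = 0.15 with an estimated correlation). Cd4, the co-receptor of helper T cells, rose by 3.80 on the log2 scale (adjusted p = 1.3e-06), and Cd8a, a chain of the co-receptor of cytotoxic T cells, by 6.59 (adjusted p = 7e-06, and 7.50 without syngeneic library 4). Among the 12 genes of cytotoxic lymphocytes, 12 rose (camera adjusted p = 3.3e-12, adjusted p = 0.098 with an estimated correlation). Nkg7 rose (log2 fold change 4.44, adjusted p = 8.3e-06). Among the 15 macrophage markers, 14 rose and 1 did not pass (15 up and 0 down adjusted over the list alone, camera adjusted p = 1.2e-11, adjusted p = 0.21 with an estimated correlation). Lysozyme, Lyz2, rose from 212 ± 62.3 to 1920 ± 184 CPM (log2 fold change 3.18, SE 0.25, adjusted p = 2.4e-06). For the 19 chemokines, 15 rose, 2 fell and 2 did not pass (16 up and 2 down adjusted over the list alone, camera adjusted p = 4e-06, adjusted p = 0.22 with an estimated correlation). Ccl8 rose (log2 fold change 3.91, adjusted p = 5.3e-06). For the 11 genes of MHC class II presentation, 9 rose and 2 did not pass (camera adjusted p = 1.3e-05, adjusted p = 0.23 with an estimated correlation). For the 10 complement genes, 8 rose and 2 did not pass (camera adjusted p = 3.8e-06, adjusted p = 0.22 with an estimated correlation). Of the 50 tested immunoglobulin and T cell receptor segments 28 rose and 1 fell.

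Type I interferon response genes in allogeneic skin numbered 17, of which 5 rose and 12 did not pass (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.00097, adjusted p = 0.51 with an estimated correlation). Th17 and follicular helper T cell genes numbered 8, of which 4 rose and 4 did not pass (camera adjusted p = 0.015, adjusted p = 0.22 with an estimated correlation). Regulatory T cell markers numbered 8, of which 3 rose and 5 did not pass (camera adjusted p = 0.023, adjusted p = 0.22 with an estimated correlation). The camera call of the list was lost without allogeneic library 2 (adjusted p = 0.05). B cell and plasma cell markers numbered 7, of which 4 rose and 3 did not pass (camera adjusted p = 0.004, adjusted p = 0.22 with an estimated correlation). Neutrophil markers numbered 8, of which 5 rose and 3 did not pass (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.24 with an estimated correlation). Their score was −0.47 in allogeneic library 2, against 3.60 and 2.69 in libraries 1 and 3 and at most −0.93 in syngeneic skin. Mast cell markers numbered 10, of which 4 rose, 1 fell and 5 did not pass (5 up and 2 down adjusted over the list alone, camera adjusted p = 0.11). The tryptase Tpsb2 rose (log2 fold change 2.29, adjusted p = 0.0034) and the receptor Mrgprb2 fell (log2 fold change −2.32, adjusted p = 0.00039).

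In the epidermis and its appendages, keratinocyte genes of wound and stress responses rose. Of the 16 stressed keratinocyte genes, 14 rose and 2 did not pass (camera adjusted p = 9e-10, adjusted p = 0.22 with an estimated correlation). Krt6a, a keratin of activated epidermis, rose from 294 ± 75.5 to 4470 ± 1730 CPM (log2 fold change 3.93, SE 0.53, adjusted p = 0.00014). Of the 18 epidermal differentiation genes, 5 rose and 13 did not pass (camera adjusted p = 0.06). Of the 8 basal keratinocyte markers, 2 rose, 1 fell and 5 did not pass (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.26). Krt14 rose (log2 fold change 1.86, adjusted p = 0.00037) while Krt15, a keratin of basal cells that is also high in the hair follicle bulge, fell from 1370 ± 653 to 116 ± 49.2 CPM (log2 fold change −3.57, SE 0.39, adjusted p = 2.8e-05). Krt71, a keratin of the inner root sheath of growing hair, fell from 4820 ± 2120 to 0.0963 ± 0.087 CPM (log2 fold change −15.50, SE 3.7, adjusted p = 0.0086), with −16.1 without allogeneic library 3, a call that limma-voom did not make (adjusted p = 0.33). Lhx2, a transcription factor of hair follicles, fell (log2 fold change −4.66, adjusted p = 0.00013, and −5.44 without allogeneic library 2). Krt33a, a keratin of the hair shaft with 0 counts in allogeneic libraries, was at least 2920-fold lower (adjusted p = 0.035). Its call was lost without each allogeneic library and without syngeneic libraries 2, 3 or 4 (adjusted p up to 0.092), with limma-voom (0.23), without the filter on low counts (0.064) and with the muscle or adipocyte score as a covariate (0.097 and 0.2).

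Matrix genes moved in both directions. Of the 36 genes of collagens and matrix assembly, 9 rose, 13 fell and 14 did not pass (12 up and 15 down adjusted over the list alone, camera adjusted p = 0.51). The fibrillar collagen gene Col1a1 (ENSMUSG00000001506) fell from 2110 ± 1180 to 392 ± 127 CPM (log2 fold change −2.43, SE 0.46, adjusted p = 0.0013), Col1a2 fell by 2.07 on the log2 scale (adjusted p = 0.0014) and Col3a1 (ENSMUSG00000026043) by 1.48 (SE 0.32, adjusted p = 0.003). Lox, an enzyme that crosslinks collagen, rose (log2 fold change 1.69, adjusted p = 0.0011). Of the 12 matrix-degrading proteases, 5 rose and 7 did not pass (camera adjusted p = 0.0062, adjusted p = 0.46 with an estimated correlation). Their score was 4.42 in allogeneic library 2, against 6.69 and 6.47 in the others and at most 4.18 in syngeneic skin. Mmp12 rose (log2 fold change 6.28, adjusted p = 2e-04). Of the 12 myofibroblast markers, 2 fell and 10 did not pass (camera adjusted p = 0.26). Fap fell (log2 fold change −1.64, adjusted p = 0.00028). Acta2 (ENSMUSG00000035783), the smooth muscle actin, did not pass (log2 fold change −0.44, adjusted p = 0.26). Of the 14 TGF-beta ligands and targets, 7 rose and 7 did not pass (camera adjusted p = 0.012, adjusted p = 0.23 with an estimated correlation). Tgfb1 rose (log2 fold change 1.15, adjusted p = 0.00021). Of the 14 SRF and MRTF targets, 3 rose, 1 fell and 10 did not pass (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.17).

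Among the 15 Wnt/beta-catenin targets in allogeneic skin, 12 fell and 3 did not pass (0 up and 14 down adjusted over the list alone, camera adjusted p = 3.5e-07, adjusted p = 0.22 with an estimated correlation). Nkd1 fell (log2 fold change −1.95, adjusted p = 0.00012), as did the transcription factor Lef1 (ENSMUSG00000027985), which went from 57.1 ± 10.3 to 4.77 ± 0.875 CPM (log2 fold change −3.58, SE 0.81, adjusted p = 0.0054). Axin2 (ENSMUSG00000000142), a widely used target gene, did not pass (log2 fold change −0.85, adjusted p = 0.11), and passed only in a fit of these groups alone (adjusted p = 0.029). Among the 16 Wnt ligands, 7 fell and 9 did not pass (camera adjusted p = 0.0064, adjusted p = 0.23 with an estimated correlation). Wnt11 fell (log2 fold change −4.53, adjusted p = 0.00042). Among the 18 Wnt receptors and secretion genes, 1 rose, 12 fell and 5 did not pass (camera adjusted p = 0.00015, adjusted p = 0.23 with an estimated correlation). Fzd1 fell (log2 fold change −1.85, adjusted p = 7.2e-05). Porcn (ENSMUSG00000031169), the target of Wnt-C59, rose from 16.9 ± 3.33 to 41.6 ± 19.7 CPM (log2 fold change 1.30, SE 0.33, adjusted p = 0.0089), but allogeneic library 2 lay inside the syngeneic range (18.9 CPM), and the call was lost with the adipocyte score as a covariate (adjusted p = 0.19). Rock2 (ENSMUSG00000020580, log2 fold change −0.04, adjusted p = 0.9), whose kinase belumosudil inhibits, and the related Rock1 (ENSMUSG00000024290, log2 fold change 0.18, adjusted p = 0.58) did not pass.

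Of the 10 endothelial markers, 8 rose and 2 did not pass (10 up and 0 down adjusted over the list alone, camera adjusted p = 2.6e-05, adjusted p = 0.23 with an estimated correlation). Pecam1 rose (log2 fold change 1.54, adjusted p = 9.1e-05). Of the 12 adipocyte markers, 3 fell and 9 did not pass (camera adjusted p = 0.022, adjusted p = 0.51 with an estimated correlation). The leptin gene Lep fell (log2 fold change −4.11, adjusted p = 0.00058, and −5.29 without allogeneic library 2). The camera call was lost without syngeneic library 3 (adjusted p = 0.083) or allogeneic library 1 (0.14). Of the 18 cell cycle genes, 6 fell and 12 did not pass (0 up and 10 down adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.46 with an estimated correlation). Tyms fell (log2 fold change −0.84, adjusted p = 0.016), a call lost without allogeneic library 3 (adjusted p = 0.099) and with the adipocyte covariate (0.065). Of the 10 aryl hydrocarbon receptor and NRF2 targets, 3 rose, 1 fell and 6 did not pass (camera adjusted p = 0.66). Hmox1 rose (log2 fold change 1.25, adjusted p = 0.00095) and the classic target Cyp1a1 fell (log2 fold change −4.78, adjusted p = 4e-05). Immediate early and heat shock genes numbered 11, of which 4 rose, 1 fell and 6 did not pass (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.076). Egr1 fell (log2 fold change −1.20, adjusted p = 0.002). Schwann cell and melanocyte markers numbered 10, of which 2 rose, 1 fell and 7 did not pass (camera adjusted p = 0.97). None of the 15 skeletal muscle markers (camera adjusted p = 0.17), 5 erythroid genes (camera adjusted p = 0.43) or 5 sex-linked check genes (camera adjusted p = 0.97) passed the edgeR test. None had an unadjusted p under 0.05 or a call by DESeq2 or limma-voom. The nearest in each were Myh2 (log2 fold change 2.57, adjusted p = 0.2), Hbb-bt (log2 fold change 1.19, adjusted p = 0.14) and Uty (log2 fold change 1.05, adjusted p = 0.43). Myh2 passed in a fit of these groups alone (adjusted p = 0.0029) and Hbb-bt without allogeneic library 2 (0.011).

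**Figure D2:**
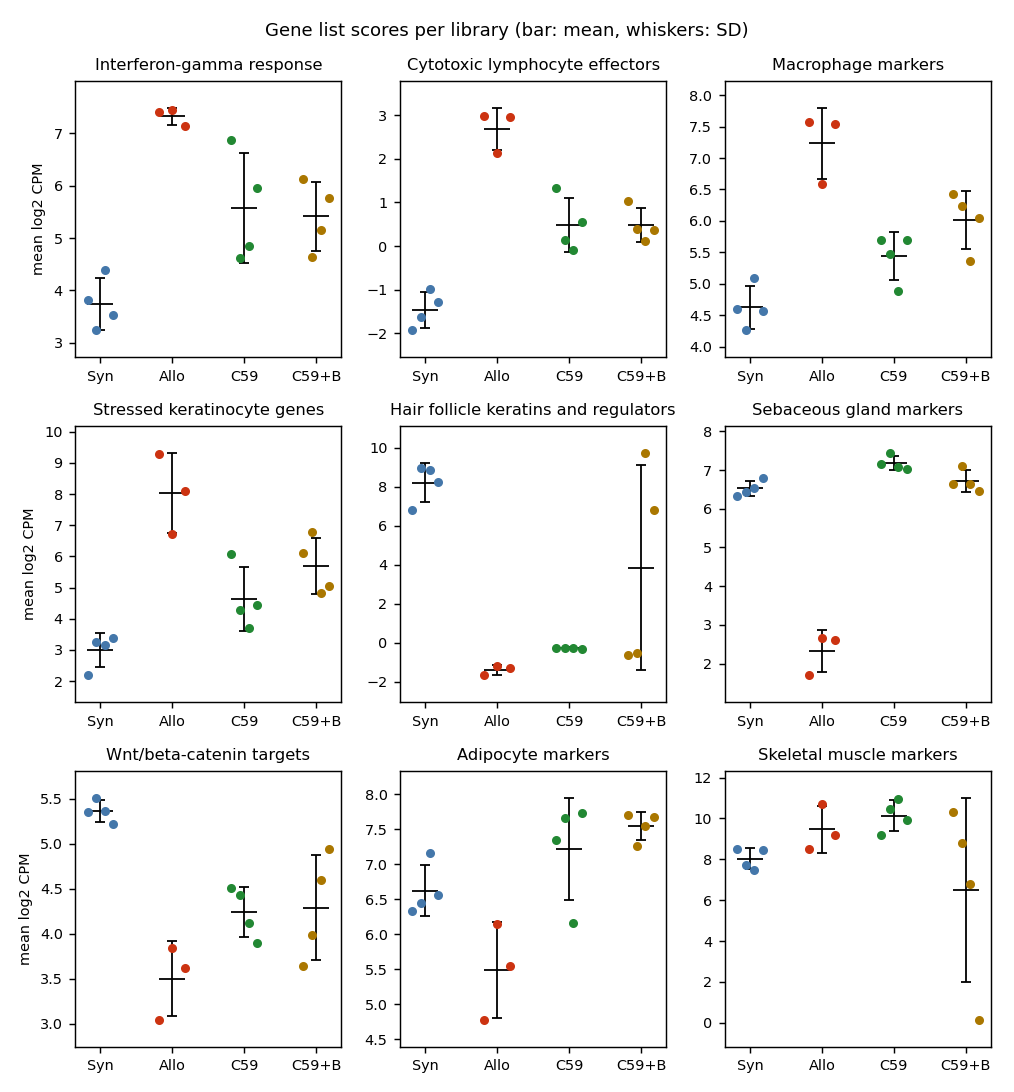
Scores (mean log2 CPM of the members) of 9 gene lists in each of the 15 libraries, one panel per list and one point per library, with bars at the group mean and whiskers of 1 SD. The hair follicle score was 9.74 and 6.80 in the combination libraries numbered 4 and 5 and −0.64 and −0.54 in those numbered 2 and 3.

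Wnt-C59 was compared with vehicle in allogeneic skin to see what the porcupine inhibitor changed. Sebaceous gland genes rose and macrophage genes fell. Far2 rose from 2.62 ± 0.531 CPM (SD, n = 3) to 316 ± 39.9 CPM (SD, n = 4; log2 fold change 6.91, SE 0.32, adjusted p = 1.4e-08). Ccl8, a chemokine for monocytes and T cells, fell from 1280 ± 142 to 106 ± 31 CPM (log2 fold change −3.60, SE 0.34, adjusted p = 5.1e-06). Of the 10 sebaceous gland markers, 9 rose and 1 did not pass (camera adjusted p = 8e-07, adjusted p = 0.096 with an estimated correlation). For the 15 macrophage markers, 15 fell (camera adjusted p = 0.00026, adjusted p = 0.86 with an estimated correlation). Mrc1, the mannose receptor, went from 401 ± 205 to 59.4 ± 14.8 CPM (log2 fold change −2.76, SE 0.39, adjusted p = 7.7e-05), and Lyz2 from 1920 ± 184 to 680 ± 170 CPM (log2 fold change −1.50, SE 0.24, adjusted p = 0.00019). In this comparison 9481 genes changed, 4586 up and 4895 down, and 5781 by at least 2-fold. These counts include whatever set treated libraries apart from vehicle libraries, such as the GC trend. With that trend removed 7177 genes were called (−1.89 for Mrc1 on the log2 scale), and 3697 with the adipocyte covariate.

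Under Wnt-C59 interferon-gamma response genes numbered 20, of which 12 fell and 8 did not pass (camera adjusted p = 0.0028, adjusted p = 0.86 with an estimated correlation). Cxcl9 went from 433 ± 215 to 57.9 ± 56.7 CPM (log2 fold change −2.90, SE 0.7, adjusted p = 0.0044, and −3.80 without Wnt-C59 library 1), a call that was lost with the adipocyte covariate (adjusted p = 0.092). T cell markers numbered 17, of which 10 fell and 7 did not pass (camera adjusted p = 0.029, adjusted p = 0.86 with an estimated correlation). The camera call was lost without allogeneic library 3 (adjusted p = 0.079) or Wnt-C59 library 2 (0.066). Cd28, a co-stimulatory receptor, fell (log2 fold change −2.90, adjusted p = 0.00031), and so did Cd3e, from 10.6 ± 2.29 to 3.93 ± 1.08 CPM (log2 fold change −1.44, SE 0.33, adjusted p = 0.0025, adjusted p = 0.063 with the adipocyte covariate). Cytotoxic lymphocyte genes numbered 12, of which 11 fell and 1 did not pass (camera adjusted p = 0.00072, adjusted p = 0.86 with an estimated correlation). Nkg7 fell (log2 fold change −1.71, adjusted p = 0.0017). Chemokines numbered 19, of which 2 rose, 11 fell and 6 did not pass (camera adjusted p = 0.054). Ccl7 fell (log2 fold change −2.48, adjusted p = 0.0028) and the lymphoid stroma chemokine Ccl19 rose (log2 fold change 3.93, adjusted p = 0.00061). Removing the GC and length trend gave log2 fold changes of −2.09 for Cd28 and 3.24 for Ccl19, and the chemokine list then passed camera (adjusted p = 0.016, adjusted p = 0.77 with an estimated correlation).

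Stressed keratinocyte genes changed as well, while collagen and matrix genes were called at near the share over all genes (50.8%). Of the 16 stressed keratinocyte genes, 15 fell and 1 did not pass (1 up and 15 down adjusted over the list alone, camera adjusted p = 0.00072, adjusted p = 0.86 with an estimated correlation). Krt6a went from 4470 ± 1730 to 774 ± 466 CPM (log2 fold change −2.53, SE 0.51, adjusted p = 0.001), a call lost with the adipocyte covariate (adjusted p = 0.2). Krt15 rose from 116 ± 49.2 to 4150 ± 1040 CPM (log2 fold change 5.17, SE 0.42, adjusted p = 2e-06) within the 8 basal keratinocyte markers, of which 4 rose, 2 fell and 2 did not pass (camera adjusted p = 0.43). Of the 23 hair follicle genes, 1 rose and 22 did not pass (camera adjusted p = 0.33). The riser was Lhx2 (log2 fold change 4.42, adjusted p = 7.7e-05, and 5.24 without allogeneic library 2). The collagen and matrix assembly list of 36 genes split, since 12 rose, 7 fell and 17 did not pass (camera adjusted p = 0.64). Elastin, Eln, rose (log2 fold change 1.97, adjusted p = 0.00013) and Lox fell (log2 fold change −2.94, adjusted p = 1.3e-05). Col1a1 rose from 392 ± 127 to 1490 ± 459 CPM (log2 fold change 1.93, SE 0.45, adjusted p = 0.0026), which was lost with the adipocyte covariate (adjusted p = 0.085). Col3a1 also passed (log2 fold change 0.85, SE 0.31, adjusted p = 0.033), but not with that covariate (0.22), in a fit of these groups alone (0.052), or without any one of allogeneic libraries 2 (0.16) and 3 (0.16) and Wnt-C59 libraries 1 (0.053), 2 (0.05) and 5 (0.067). Without the GC and length trend, log2 fold changes were −3.18 for Krt6a, 4.44 for Krt15, 3.54 for Lhx2, 1.30 for Eln and −2.25 for Lox.

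Contractile, TGF-beta and Wnt genes split under Wnt-C59. Of the 12 myofibroblast markers, 5 rose, 1 fell and 6 did not pass (camera adjusted p = 0.31). Myl9 rose (log2 fold change 2.26, adjusted p = 5.3e-05), as did Acta2 (log2 fold change 1.55, SE 0.3, adjusted p = 0.00062). Of the 14 SRF and MRTF targets, 6 rose, 2 fell and 6 did not pass (camera adjusted p = 0.36). Of the 14 TGF-beta ligands and targets, 2 rose, 5 fell and 7 did not pass (camera adjusted p = 0.58). Ltbp2 rose (log2 fold change 2.03, adjusted p = 1.4e-05) and the receptor Tgfbr1 fell (log2 fold change −1.91, adjusted p = 7.8e-06). Of the 16 Wnt ligands, 8 rose, 1 fell and 7 did not pass (camera adjusted p = 0.029, adjusted p = 0.86 with an estimated correlation). Wnt5b rose (log2 fold change 1.97, adjusted p = 0.00033). With the GC and length trend removed, 2 of the Wnt ligands rose and 1 fell (camera adjusted p = 0.26), the receptor and secretion list passed camera (0.016, adjusted p = 0.77 with an estimated correlation), and log2 fold changes were 1.52 for Myl9, −0.77 for Tgfbr1, 0.94 for Wnt5b, 1.49 for Fzd2, −0.59 for Lrp6, −0.94 for Rock1 and −1.71 for Porcn. Of the 15 Wnt/beta-catenin targets, 5 rose, 1 fell and 9 did not pass (camera adjusted p = 0.08). Nkd1 rose (log2 fold change 1.67, adjusted p = 0.00016). The camera test passed without allogeneic library 2 (adjusted p = 0.037) or Wnt-C59 library 5 (0.042; adjusted p = 0.87 and 0.82 with an estimated correlation). Of the 18 Wnt receptors and secretion genes, 8 rose, 2 fell and 8 did not pass (9 up and 3 down adjusted over the list alone, camera adjusted p = 0.11). Fzd2 rose (log2 fold change 2.10, adjusted p = 1.3e-05) and the co-receptor Lrp6 fell (log2 fold change −1.56, adjusted p = 9.6e-05). Axin2 (log2 fold change 0.72, adjusted p = 0.13, adjusted p = 0.037 without Wnt-C59 library 5) and Lef1 (log2 fold change −0.37, adjusted p = 0.71) did not pass. Rock1 fell from 92.2 ± 15.2 to 20.2 ± 4.27 CPM (log2 fold change −2.19, SE 0.23, adjusted p = 8.8e-06). Rock2 fell as well (log2 fold change −1.61, adjusted p = 9.4e-06), but with the GC and length trend removed its log2 fold change was −0.32 (adjusted p = 0.084). Porcn fell (log2 fold change −1.01, SE 0.33, adjusted p = 0.019), a call lost with the adipocyte covariate (0.61), in a fit of these groups alone (0.066) and without allogeneic libraries 1 (0.088) or 3 (0.1) or Wnt-C59 libraries 2 (0.054) or 4 (0.052).

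Adipocyte markers numbered 12, of which 10 rose and 2 did not pass (11 up and 0 down adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.86 with an estimated correlation). The fat cell regulator Pparg rose (log2 fold change 1.87, adjusted p = 2.2e-05). Cell cycle genes numbered 18, of which 2 rose, 8 fell and 8 did not pass (camera adjusted p = 0.18). Mki67 fell (log2 fold change −2.10, adjusted p = 0.00091, adjusted p = 0.14 with the adipocyte covariate). Mast cell markers numbered 10, of which 1 rose, 6 fell and 3 did not pass (1 up and 8 down adjusted over the list alone, camera adjusted p = 0.08). Mrgprb2 rose (log2 fold change 1.91, adjusted p = 0.00066). Erythroid genes numbered 5, of which 4 rose and 1 did not pass (5 up and 0 down adjusted over the list alone, camera adjusted p = 0.08). These calls were lost with the GC and length trend removed (adjusted p = 0.086 for Hbb-bs, 0.1 for Hba-a2, 0.15 for Alas2 and 0.17 for Hba-a1), while log2 fold changes were −1.16 for Mki67, 2.62 for Mrgprb2 and −1.05 for Xist. Xist, the RNA of the inactive X chromosome, fell (log2 fold change −2.65, adjusted p = 2.7e-05), and the other 4 sex-linked check genes did not pass (camera adjusted p = 0.43). None of the 15 skeletal muscle markers passed (0 at an unadjusted p under 0.05, with DESeq2 or limma-voom, camera adjusted p = 0.69). Ckm was the nearest (log2 fold change 1.39, adjusted p = 0.4, and 0.0065 with the muscle covariate, circular as it holds Ckm). Chil4 had 0 counts under Wnt-C59 and was at least 2100-fold lower (adjusted p = 0.0017). Alb, the albumin of the liver, rose by 10.28 on the log2 scale (adjusted p = 0.0094) but by 4.94 without Wnt-C59 library 4, which held 1180 CPM, and limma-voom did not call it (0.31).

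**Figure D3:**
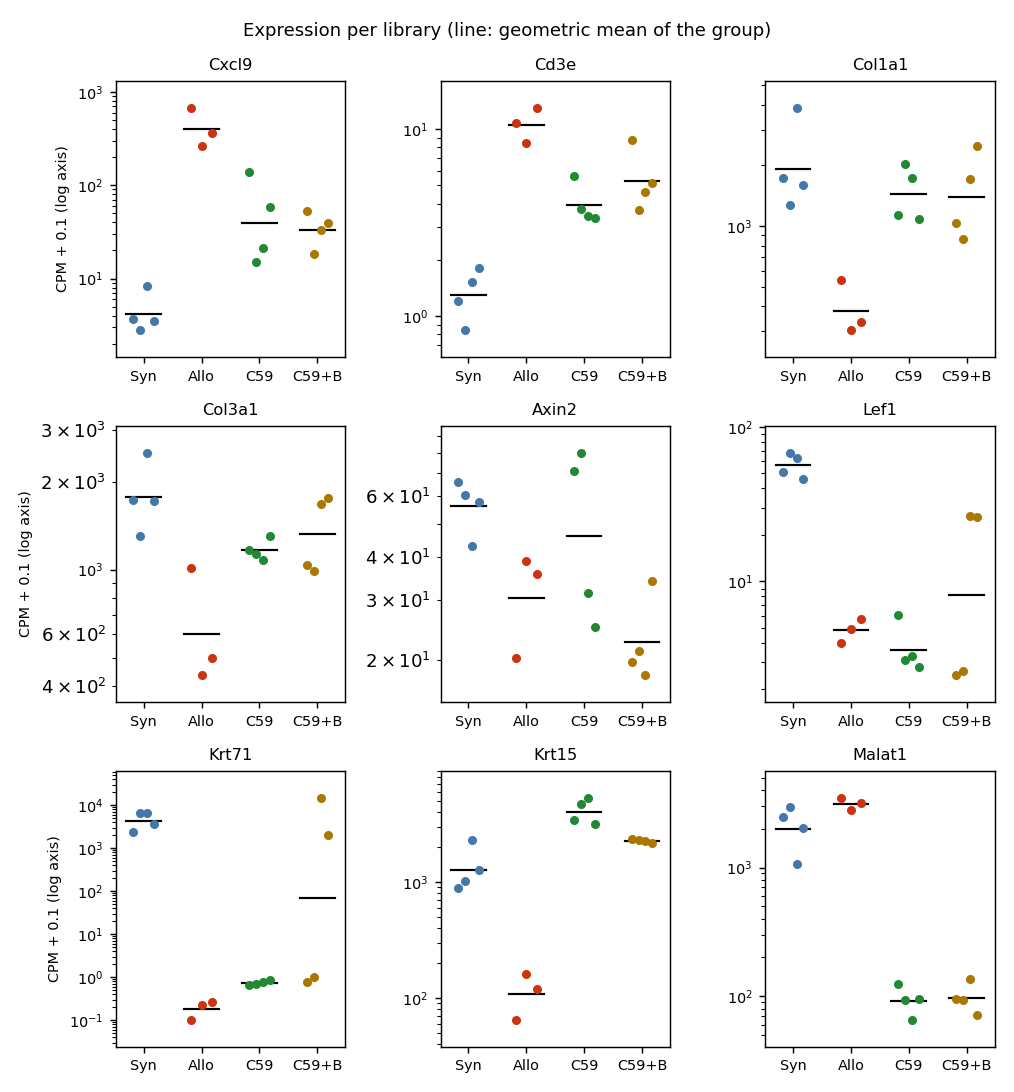
Expression of 9 genes (CPM plus 0.1 on a log axis) in each of the 15 libraries by group, with a line at the geometric mean of each group. Malat1 lay at 1070 to 3500 CPM in vehicle libraries and at 65 to 136 CPM in treated libraries.

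The combination was compared with vehicle in allogeneic skin to see what both inhibitors changed together. Sebaceous gland genes rose and interferon-gamma response genes fell. Far2 rose to 190 ± 69.7 CPM (SD, n = 4; log2 fold change 6.17, SE 0.31, adjusted p = 3.3e-08) from 2.62 ± 0.531 CPM (SD, n = 3). Elastin, Eln, rose from 36.4 ± 7.72 to 223 ± 55.1 CPM (log2 fold change 2.61, SE 0.31, adjusted p = 1.7e-05), and Ccl8 fell to 209 ± 82.5 CPM (log2 fold change −2.62, SE 0.33, adjusted p = 2.3e-05). Of the 10 sebaceous gland markers, 8 rose and 2 did not pass (camera adjusted p = 1.9e-05, adjusted p = 0.19 with an estimated correlation). Of the 20 interferon-gamma response genes, 13 fell and 7 did not pass (camera adjusted p = 0.004, adjusted p = 0.96 with an estimated correlation). Cxcl9 fell to 35.8 ± 14.4 CPM (log2 fold change −3.60, SE 0.72, adjusted p = 0.0011), which was lost with the adipocyte covariate (adjusted p = 0.066), and Gbp7 fell (log2 fold change −4.58, adjusted p = 4.3e-05). In total 10168 genes changed (54.5% of those tested), 5055 up and 5113 down, and 6530 by at least 2-fold. As for Wnt-C59 alone, the treated libraries differ from vehicle libraries in more than the drugs, and 7546 genes were called with the GC and length trend removed (1.92 for Eln and −3.39 for Gbp7 on the log2 scale) and 3454 with the adipocyte covariate.

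Hair follicle genes under the combination differed between libraries of the same group. Of the 23 genes, 20 rose and 3 did not pass (23 up and 0 down adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.96 with an estimated correlation). But without the libraries numbered 4 and 5, 6 rose and 1 fell (camera adjusted p = 0.23). Krt71 lay at 15100 and 2000 CPM in the libraries numbered 4 and 5 and at 0.659 and 0.914 CPM in those numbered 2 and 3 (log2 fold change 15.33, SE 3.7, adjusted p = 0.0042 for the whole group, 12.6 without library 4, 2.93 without both, 14.50 with the GC and length trend removed, and 16 without allogeneic library 3), and it was not called with limma-voom (adjusted p = 0.51) or the adipocyte covariate (0.084). The same libraries stood apart in skeletal muscle, with scores of 6.79 in library 4 and 0.13 in library 5 against 10.34 and 8.82 in libraries 2 and 3. None of the 15 muscle markers passed (0 at an unadjusted p under 0.05, 0 with DESeq2, 1 with limma-voom, camera adjusted p = 0.14). Tnnt3 was the nearest (log2 fold change −1.85, adjusted p = 0.22, and 0.00092 with the muscle covariate, which holds Tnnt3). Lhx2 rose in the group (log2 fold change 4.67, adjusted p = 4.5e-05, 5.51 without allogeneic library 2 and 3.74 with that trend removed).

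No matrix, contractile, TGF-beta or Wnt list passed camera under the combination. Of the 36 genes of collagens and matrix assembly, 17 rose, 5 fell and 14 did not pass (camera adjusted p = 0.053). Lox fell (log2 fold change −2.42, adjusted p = 3.4e-05). Col1a1 went from 392 ± 127 to 1520 ± 743 CPM (log2 fold change 1.96, SE 0.45, adjusted p = 0.0021, and 0.14 with the adipocyte covariate). Without combination libraries 4 and 5 the log2 fold change was 1.28. Col3a1 passed (log2 fold change 1.07, SE 0.31, adjusted p = 0.0096), but not with that or the hair follicle covariate (0.17 and 0.15). It also failed without allogeneic library 2 (0.055) or 3 (0.057) or combination libraries 4 and 5 (0.15). Of the 12 myofibroblast markers, 6 rose and 6 did not pass (camera adjusted p = 0.34). Acta2 rose (log2 fold change 1.41, SE 0.29, adjusted p = 0.001), a call lost with the adipocyte covariate (adjusted p = 0.13). Of the 14 SRF and MRTF targets, 7 rose, 2 fell and 5 did not pass (camera adjusted p = 0.064). Tgfb1i1 rose (log2 fold change 1.39, adjusted p = 1e-05). Of the 14 TGF-beta ligands and targets, 4 rose, 4 fell and 6 did not pass (camera adjusted p = 0.96). Ccn2 rose (log2 fold change 1.18, adjusted p = 0.0014) and Tgfbr1 fell (log2 fold change −1.86, adjusted p = 6.7e-06). Of the 16 Wnt ligands, 10 rose, 1 fell and 5 did not pass (camera adjusted p = 0.053). Wnt5b rose (log2 fold change 2.48, adjusted p = 5.2e-05). Of the 15 Wnt/beta-catenin targets, 8 rose, 1 fell and 6 did not pass (camera adjusted p = 0.078). Scores were 4.59 and 4.94 in libraries 4 and 5, 3.64 and 3.99 in 2 and 3, and at most 3.84 in allogeneic skin. Nkd1 rose (log2 fold change 1.24, adjusted p = 0.0011, and 0.21 with the adipocyte covariate). Camera passed without allogeneic (adjusted p = 0.039) or combination library 2 (0.026), but not with an estimated correlation (0.96 and 0.9). Of the 18 Wnt receptors and secretion genes, 9 rose, 2 fell and 7 did not pass (camera adjusted p = 0.15). Fzd8 rose (log2 fold change 1.73, adjusted p = 1e-05) and Lrp6 fell (log2 fold change −1.64, adjusted p = 5.2e-05). Once the GC and length trend was removed, 3 Wnt ligands rose and 1 fell, 4 Wnt targets rose and 0 fell, camera called the collagen (0.0028) and Wnt receptor (0.012) lists (adjusted p = 0.87 for both with an estimated correlation), and log2 fold changes were −1.61 for Lox, −0.55 for Tgfbr1, 1.39 for Wnt5b and −0.55 for Lrp6.

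Of the genes followed in each comparison, Rock1 fell from 92.2 ± 15.2 to 15.6 ± 2.66 CPM (log2 fold change −2.56, SE 0.23, adjusted p = 3.1e-06). Rock2 fell (log2 fold change −1.59, adjusted p = 7.7e-06), with log2 fold changes of −1.10 for Rock1 and −0.11 for Rock2 once the GC and length trend was removed (Rock2 adjusted p = 0.54). Porcn did not pass (log2 fold change −0.69, SE 0.33, adjusted p = 0.091), but passed without allogeneic library 2 (0.0091), without combination library 4 (0.05) and with the trend removed (0.0048). Axin2 did not pass (log2 fold change −0.44, adjusted p = 0.34). Lef1 did not pass either (log2 fold change 1.58, adjusted p = 0.089), passed with DESeq2 (adjusted p = 0.027) and without combination libraries 2 (0.019) or 3 (0.023), and turned to −0.943 without the libraries numbered 4 and 5 (adjusted p = 0.035). Cd3e fell to 5.45 ± 2.19 CPM (log2 fold change −0.96, SE 0.33, adjusted p = 0.023). That call was lost with the muscle or adipocyte covariate (0.054 and 0.2), with the GC and length trend removed (0.078), with the hair follicle covariate (0.15), without libraries 4 and 5 (0.14), and without allogeneic library 1 (0.053) or 3 (0.1) or combination library 3 (0.062), 4 (0.054) or 5 (0.052).

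Immune lists under the combination fell or split. Among the 11 MHC class II genes, 3 rose, 1 fell and 7 did not pass (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.56). Among the 8 regulatory T cell markers, 3 rose, 3 fell and 2 did not pass (camera adjusted p = 0.89). Among the 12 cytotoxic lymphocyte genes, 9 fell and 3 did not pass (0 up and 10 down adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.96 with an estimated correlation). The transcription factor Eomes fell (log2 fold change −3.23, adjusted p = 0.0011). Among the 15 macrophage markers, 11 fell and 4 did not pass (camera adjusted p = 0.021, adjusted p = 0.96 with an estimated correlation). Lyz2 fell (log2 fold change −1.42, adjusted p = 0.00023). The camera call was lost without allogeneic library 3 (adjusted p = 0.052), combination library 4 (0.052) or the combination libraries 4 and 5 (0.18). Among the 17 T cell markers, 1 rose, 8 fell and 8 did not pass (camera adjusted p = 0.16). Cd28 fell (log2 fold change −3.01, adjusted p = 0.00019). Among the 19 chemokines, 4 rose, 8 fell and 7 did not pass (camera adjusted p = 0.5). Ccl19 rose (log2 fold change 4.54, adjusted p = 0.00021). Among the 16 stressed keratinocyte genes, 1 rose, 8 fell and 7 did not pass (1 up and 9 down adjusted over the list alone, camera adjusted p = 0.053). Among the 8 basal keratinocyte markers, 3 rose, 3 fell and 2 did not pass (camera adjusted p = 0.82). Krt15 rose (log2 fold change 4.29, adjusted p = 3.9e-06). Among the 12 adipocyte markers, 11 rose and 1 did not pass (camera adjusted p = 0.002, adjusted p = 0.96 with an estimated correlation). The leptin gene Lep rose (log2 fold change 4.07, 5.29 without allogeneic library 2, adjusted p = 0.00023, 0.065 with the adipocyte covariate, which holds Lep). Among the 11 immediate early and heat shock genes, 5 rose and 6 did not pass (camera adjusted p = 0.038, adjusted p = 0.96 with an estimated correlation). Egr1 rose (log2 fold change 2.01, adjusted p = 2.3e-05). The camera call was lost without allogeneic library 2 (adjusted p = 0.077), without combination library 3 (0.052) and with the GC and length trend removed (0.54). That removal gave log2 fold changes of −1.99 for Cd28, 3.63 for Ccl19 and 3.45 for Krt15, and camera then called the T cell (0.0072) and stressed keratinocyte (0.0038) lists (adjusted p = 0.91 for both with an estimated correlation). Cyp1a1 rose (log2 fold change 5.51, adjusted p = 6.7e-06), and Chil4 was lower, with a ratio of vehicle to combination of 9090 (95% counting interval 3110 to 44100) (adjusted p = 0.0016, lost with the adipocyte covariate, 0.33, and the hair follicle covariate, 0.31; −12.1 without allogeneic library 1 and −13.8 without combination library 2).

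The combination was compared with Wnt-C59 alone to see what belumosudil added, and few genes passed. In the edgeR test 43 genes changed, 19 up and 24 down, while 3892 had an unadjusted p under 0.05, DESeq2 called 1507 and limma-voom 60. Ucp3, a mitochondrial carrier of muscle and brown fat, fell from 27.2 ± 7.14 CPM (SD, n = 4) to 5.25 ± 1.6 CPM (SD, n = 4; log2 fold change −2.37, SE 0.31, adjusted p = 0.018). Igfbp3, which binds insulin-like growth factors, fell from 217 ± 34.8 to 90.1 ± 16.4 CPM (log2 fold change −1.27, SE 0.19, adjusted p = 0.021). Smox, an enzyme that oxidizes spermine, rose (log2 fold change 1.56, SE 0.23, adjusted p = 0.022), and so did Pmepa1, a target of TGF-beta (log2 fold change 1.13, adjusted p = 0.046). Between 1 gene (without combination library 3) and 45 genes (without combination library 4) were called when single libraries were left out, with 3 without Wnt-C59 library 1 or 2, 5 without Wnt-C59 library 5, 12 without Wnt-C59 library 4, and 17 without combination library 2. Without combination library 3 each of these 4 genes was lost (adjusted p of 0.053 for Ucp3, 0.053 for Igfbp3, 0.077 for Smox and 0.077 for Pmepa1), and all but Ucp3 were also lost without Wnt-C59 library 1 or 2, all but Ucp3 and Igfbp3 without Wnt-C59 library 5, and Pmepa1 without Wnt-C59 library 4 (0.091) and without combination library 2 (0.055) or 4 (0.055). The muscle covariate ended the calls of Igfbp3 (0.066) and Pmepa1 (0.066), a fit of these groups alone those of Smox (0.055) and Pmepa1 (0.07), and the adipocyte covariate that of Pmepa1 (0.053). Counts under other settings were 9 with the muscle covariate, 18 in a fit of these groups alone, 141 with the GC and length trend removed, 380 without the combination libraries 4 and 5, and 403 with the hair follicle covariate.

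In the list tests between the treated groups that follow, none of the members passed over all genes. For the 10 mast cell markers, 0 passed (9 at an unadjusted p under 0.05, 7 with DESeq2, 2 with limma-voom, 8 up and 1 down adjusted over the list alone, camera adjusted p = 9.1e-06, adjusted p = 0.53 with an estimated correlation). Mcpt4 did not pass (log2 fold change 2.30, adjusted p = 0.065, 0.022 without Wnt-C59 library 2 and 0.048 with the GC and length trend removed) and Tpsb2 did not pass (log2 fold change 2.28, adjusted p = 0.065, and 0.03 without Wnt-C59 library 1). DESeq2 and limma-voom called both. For the 36 collagens and matrix genes, 0 passed (14 at an unadjusted p under 0.05, 7 with DESeq2, 0 with limma-voom, 6 up and 0 down adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.53 with an estimated correlation). Tnc did not pass (log2 fold change 3.48, adjusted p = 0.069, called by DESeq2 and without libraries 4 and 5). For the 15 macrophage markers, 19 chemokines and 16 stressed keratinocyte genes, 0 passed (in this order 5, 8 and 6 at an unadjusted p under 0.05). DESeq2 called 2, 6 and 3 of them and limma-voom 0. Adjusted over each list alone, 2, 7 and 3 rose and 0 fell. Camera adjusted p was 0.00098, 0.00098 and 8e-04 (adjusted p = 0.53 for each with an estimated correlation). For the 14 SRF and MRTF targets, 0 passed (8 at an unadjusted p under 0.05, 5 with DESeq2, 0 with limma-voom, 4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.53 with an estimated correlation). Zyx did not pass (log2 fold change 0.81, adjusted p = 0.055, and 0.025 with the trend removed). For the 11 immediate early and heat shock genes and the 5 erythroid genes, 0 passed (4 of each at an unadjusted p under 0.05, 2 and 4 with DESeq2, 0 with limma-voom). Adjusted over the list alone, 2 of the first rose and 0 fell, and 0 of the second rose and 4 fell. Camera adjusted p was 0.0012 and 8e-04 (adjusted p = 0.53 for both with an estimated correlation).

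Other list calls between the treated groups were lost, or turned, without certain libraries. For the 23 hair follicle genes, 0 passed (21 at an unadjusted p under 0.05, 19 with DESeq2, 0 with limma-voom, 21 up and 0 down adjusted over the list alone, camera adjusted p = 6.4e-07, adjusted p = 0.53 with an estimated correlation), which without the combination libraries 4 and 5 turned to the other direction (camera adjusted p = 0.38). For the 15 skeletal muscle markers, 0 passed (0 at an unadjusted p under 0.05, 0 with DESeq2, 0 with limma-voom, camera adjusted p = 1.1e-05, adjusted p = 0.53 with an estimated correlation), lost without those libraries (0.18). For the 10 endothelial markers and 18 cell cycle genes, 0 passed (3 and 6 at an unadjusted p under 0.05, 1 and 0 with DESeq2, 0 with limma-voom). Camera adjusted p was 0.0027 and 0.00094 (adjusted p = 0.53 for both with an estimated correlation). Both calls were lost without those libraries (0.62 and 0.61), the second also without combination library 5 (0.088). For the 11 MHC class II genes, 0 passed (1 at an unadjusted p under 0.05, 0 with DESeq2, 0 with limma-voom, camera adjusted p = 0.0099, adjusted p = 0.55 with an estimated correlation), lost without Wnt-C59 library 2 (0.084) or combination library 2 (0.23). For the 12 proteases, 0 passed (4 at an unadjusted p under 0.05, 2 with DESeq2, 0 with limma-voom, 2 up and 0 down adjusted over the list alone, camera adjusted p = 0.0069, adjusted p = 0.55 with an estimated correlation), lost without combination library 2 (0.059). For the 10 sebaceous gland markers, 0 passed (2 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom, 0 up and 1 down adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.53 with an estimated correlation), lost without Wnt-C59 library 2, combination library 2 or 5, or the combination libraries 4 and 5 (0.34). For the 15 Wnt/beta-catenin targets, 0 passed (2 at an unadjusted p under 0.05, 2 with DESeq2, 0 with limma-voom, camera adjusted p = 0.97), which turned downward without the combination libraries 4 and 5 (camera adjusted p = 0.035, adjusted p = 0.65 with an estimated correlation). Cxcl9 (log2 fold change −0.69, adjusted p = 0.56), Cd3e (log2 fold change 0.47, adjusted p = 0.4), Col1a1 (log2 fold change 0.03, adjusted p = 0.98), Col3a1 (log2 fold change 0.22, adjusted p = 0.69), Acta2 (log2 fold change −0.14, adjusted p = 0.79), Porcn (log2 fold change 0.33, adjusted p = 0.57), Rock1 (log2 fold change −0.37, adjusted p = 0.32) and Rock2 (log2 fold change 0.02, adjusted p = 0.97) did not pass, nor did Axin2 (log2 fold change −1.16, adjusted p = 0.11) and Lef1 (log2 fold change 1.95, adjusted p = 0.14), which DESeq2 called.

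Both treated groups were compared with syngeneic skin as a secondary question, how far treated skin lay from skin without graft-versus-host disease. Under Wnt-C59 9898 genes differed from syngeneic skin, 4854 up and 5044 down, and under the combination 10081, 5013 up and 5068 down, again across treated and vehicle libraries. T cell markers stayed above the syngeneic level. Of 17 under Wnt-C59, 14 rose and 3 did not pass (15 up and 0 down adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.55 with an estimated correlation). Under the combination 15 rose and 2 did not pass (camera adjusted p = 5.6e-06, adjusted p = 0.47 with an estimated correlation). Interferon-gamma response genes counted 20, of which under Wnt-C59 16 rose and 4 did not pass (18 up and 0 down adjusted over the list alone, camera adjusted p = 1e-04, adjusted p = 0.55 with an estimated correlation) and under the combination 12 rose and 8 did not pass (13 up and 0 down adjusted over the list alone, camera adjusted p = 0.00042, adjusted p = 0.66 with an estimated correlation). Hair follicle genes counted 23, of which under Wnt-C59 22 fell and 1 did not pass (camera adjusted p = 1e-05, adjusted p = 0.55 with an estimated correlation) and under the combination 0 passed (0 at an unadjusted p under 0.05, 0 with DESeq2, 16 with limma-voom, camera adjusted p = 0.0085, adjusted p = 0.71 with an estimated correlation). Without the combination libraries 4 and 5, 22 of the 23 hair follicle genes fell under the combination. Wnt/beta-catenin targets counted 15, of which under Wnt-C59 9 fell and 6 did not pass (camera adjusted p = 0.012, adjusted p = 0.55 with an estimated correlation) and under the combination 11 fell and 4 did not pass (camera adjusted p = 0.0085, adjusted p = 0.66 with an estimated correlation). Sebaceous gland markers counted 10, of which under Wnt-C59 6 rose, 1 fell and 3 did not pass (camera adjusted p = 0.13) and under the combination 3 rose, 1 fell and 6 did not pass (camera adjusted p = 0.5).

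Reversal was measured over the 5556 genes that differed between allogeneic and syngeneic skin. Under Wnt-C59 1443 genes that had risen fell and 1593 that had fallen rose, against 717 and 694 for independent lists, which leave out the shared allogeneic libraries, and 96 rose further and 161 fell further, against 672 and 741. Under the combination 1354 genes fell and 1807 rose in the opposite direction, against 749 and 765, and 151 and 123 went on in the same direction, against 740 and 774. In 20 simulations without effect 0 genes were called in opposite directions, but few can be called at all there. Across 18651 genes, which are not independent replicates, the covariance of the log2 fold changes was −0.97 for Wnt-C59 and −1.32 for the combination, against −0.162 in simulations without effect, a difference of −0.808 and −1.15. Pearson's r was −0.485 and −0.609, against −0.576 and −0.575 in the simulations, and 82.0% and 81.8% of the 5556 genes had the opposite sign, against 82.2% and 82.3%. Without effect shared noise alone sets both, so simulations give no baseline for them. Since 3 allogeneic libraries cannot be split into groups of at least 2, part of the excess in counts may come from the shared controls. On the line from the syngeneic mean at 0 to the allogeneic mean at 1, Wnt-C59 libraries lay at 0.479 ± 0.079 (SD, n = 4) and combination libraries at 0.412 ± 0.23 (SD, n = 4). Over genes that had risen these were 0.349 ± 0.19 and 0.45 ± 0.12, and over genes that had fallen 0.722 ± 0.0069 and 0.431 ± 0.42. Allogeneic libraries 1, 2 and 3, each held out of the line and of the choice of genes, lay at 1.036, 0.75 and 0.984. The Wnt-C59 value was 0.316 without allogeneic library 2. The combination libraries numbered 4 and 5 lay at 0.132 and 0.315, those numbered 2 and 3 at 0.622 and 0.579.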

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

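The tests on a GC and length trend, on treatment, on a swap, on follicles against the other treated libraries, on a superficial piece of skin and on normalization were chosen after the result was seen. The tests on a batch, on follicles against the other 9 libraries and on the share of fibroblasts were not.

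Of 135 values tested within groups of 4 libraries, scores of 35 lists and levels of 10 genes, 5 lay far from the others of their group, and chance gives about 6.8 at 1 in 20. The MHC class II score was 5.94 in Wnt-C59 library 2, against 6.57 to 6.66 in the other libraries of its group. The score of Th17 and follicular helper T cell genes was 2.43 in syngeneic library 2, against 2.74 to 2.78. The chemokine score was 2.13 in syngeneic library 3, against 1.31 to 1.43. The TGF-beta score was 5.30 in Wnt-C59 library 1, against 4.96 to 4.99. The cell cycle score was 5.66 in syngeneic library 1, against 5.41 to 5.42.

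All 8 treated libraries stood apart from all 7 vehicle libraries, and 4803 genes moved the same way in both treated groups against both vehicle groups. A GC and length trend may account for much of this but not for all of it, since 1658 of the 4803 genes (34.5%) were still called so with the trend removed, among 2296 called in all. A batch of library preparation, sequencing or quantification would leave genes at 0 on one side and at 1 CPM or more in every library of the other, and 11 such genes were found, all 11 at 0 in vehicle libraries and all 11 unnamed or pseudogenes. Between allogeneic and syngeneic skin, both under vehicle, 104 genes parted in this way, 70 of them named, but fewer libraries had to agree there. The 11 genes go with a batch but do not exclude treatment. Treatment and any batch that follows the same split cannot be told apart.

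Hair follicle genes were high in combination libraries 4 and 5, whose score rose by 10.44 and 7.51 over the mean of the other 9 allogeneic and treated libraries. A swap with syngeneic libraries is excluded, since Malat1 was at most 136 CPM in libraries 4 and 5 against at least 1070 CPM in syngeneic skin, and no syngeneic library had a hair score under 6.78. More follicles of every kind than in the other 6 treated libraries is excluded too, since the score of 9 follicle markers outside hair growth (Krt15 and Lgr5 among them also stand in other lists) rose by at most 0.30 and at least 0.11 there (SD 0.25) while the hair score rose by 7.18 to 10.11. Against all 9 other libraries the markers rose by 1.15 to 1.33 (SD 1.60), which leaves that explanation open for them. A more superficial piece of skin stays open, since the muscle score lay at −1.71 and −8.37 against the lowest of the other 9. Against it, adipocyte scores were not low (7.55 and 7.67, against 4.77 to 7.73 there). The combination treatment stays open too, since only 2 of its 4 libraries had a hair score above every allogeneic and Wnt-C59 library. A different phase of hair growth was not tested.

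Col1a1 and Col1a2 fell in allogeneic skin by 2.25 on the log2 scale on average. Of 12 fibroblast markers other than collagens (median log2 fold change −0.51, SD 1.2), 3 fell (Dpt at −1.15, Pi16 at −2.80 and Mfap4 at −3.19) and 0 rose at an edgeR adjusted p under 0.05. This excludes an even loss of fibroblasts as sole cause, not a loss of some. Normalization stays open, since the smaller of both falls was −2.06 with other size factors but these moved the median of all genes only from −0.0674 to −0.0611 and −0.0604. A GC and length trend as the whole cause is excluded as well, since the smaller fall was −1.92 with the trend removed. A change in the fibroblasts of allogeneic skin was not tested.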

How the results depend on the processing

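The removal of the GC and length trend, the fits without combination libraries 4 and 5, the hair follicle covariate and the block on treated column numbers were chosen after seeing the data. With DESeq2 size factors 524 results on named genes kept their direction and side of the threshold and 2 were lost, and with TMMwsp 525 kept them and 1 was lost. Over all alternatives that leave out no single library, such results held in 5374 cases, were lost in 413, gained in 75 and reversed in 16; with single libraries left out they held in 3457, were lost in 304 and gained in 10. Results on lists held in 631 cases, were lost in 112, gained in 58 and reversed in 4; with single libraries left out they held in 1492, were lost in 30 and gained in 53. At the depth and number of libraries used, 24.6% of simulated 2-fold changes were recovered for allogeneic against syngeneic skin, and depth was not varied.

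With the adipocyte covariate 3157, 3697 and 3454 genes were called for allogeneic against syngeneic and for Wnt-C59 and the combination against allogeneic, 2982, 3596 and 3348 of them also without it. A minimum of 2-fold left 3511, 5781 and 6530 genes there, and 5625 and 5772 for Wnt-C59 and the combination against syngeneic skin, since fewer genes can pass. For the combination against Wnt-C59, in place of 43 genes, DESeq2 called 1507, the muscle covariate 9, a fit of both groups alone 18, the fit with the GC and length trend removed 141, the fit without combination libraries 4 and 5 380, the hair follicle covariate 403, and fits without single libraries 1 to 45. The cause was not tested.

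With an estimated correlation camera called 0 lists in every comparison, in place of 23, 8, 7, 15, 14 and 18 in the order of the comparisons given in the report. Fry called 15 lists for Wnt-C59 and 14 for the combination against allogeneic skin, 0 for the combination against Wnt-C59 and 22 for Wnt-C59 against syngeneic skin. For the combination against allogeneic skin 11 lists were called with the GC and length trend removed and 6 to 12 without single libraries. The position of Wnt-C59 libraries between syngeneic and allogeneic skin was 0.316 to 0.419 without single allogeneic libraries. The cause was not tested.

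Directions that reversed were these. With the adipocyte covariate, Wnt-C59 against allogeneic: Cxcl3 1.08, Il6 0.0213 and Ngp 0.0671. With the GC and length trend removed, Wnt-C59 against allogeneic: Ikzf2 0.0703, Egfl7 −0.0486, Plvap −0.0493, Hspa1b −0.0221, Ier2 −0.296 and Gclm 0.273. With the trend removed, combination against allogeneic: Wnt10a −0.0694, Plvap −0.339, Egfl7 −0.425, Sox10 −0.197 and Srxn1 −0.0318. Lef1 for the combination against allogeneic was −0.943 without combination libraries 4 and 5 and −1.08 with the hair follicle covariate. Without those libraries the camera direction of 3 lists turned, with adjusted p of 0.035 (Wnt targets) and 0.38 (hair follicle genes) for the combination against Wnt-C59 and of 0.013 (muscle, whose median was above 0 before and after) for the combination against syngeneic skin. The cause was not tested.

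With the replicate number as a block 2968 genes were called between allogeneic and syngeneic skin, 2662 of them also without it, and 27 lists. The numbers do not pair the libraries, since same-numbered libraries correlated at −0.0478, −0.143 and 0.00835, and allogeneic libraries 1, 2 and 3 correlated best with syngeneic libraries 2, 4 and 2. Treated columns carry other numbers than the labels. With these as a block 0 genes were called for the combination against Wnt-C59, and 18 lists, with interferon-gamma genes turned (camera adjusted p = 0.0015, adjusted p = 0.72 with an estimated correlation). Libraries numbered 2, 4 and 5 correlated at 0.0536, 0.0224 and 0.111 and best with Wnt-C59 libraries 4, 4 and 1, so these numbers do not pair them.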

Other observations

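Tests of other splits were set before their result was seen for the combination against allogeneic and syngeneic skin, and after it for the other 4 comparisons.

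Further lists were tested between treated and vehicle skin, which also differ technically, and those on neutrophils, proteases and collagens did not pass camera. Neutrophil markers numbered 8, of which against allogeneic skin under Wnt-C59 6 fell and 2 did not pass (1 up and 7 down adjusted over the list alone, camera adjusted p = 0.22) and under the combination 3 fell and 5 did not pass (camera adjusted p = 0.27). Matrix-degrading proteases numbered 12, of which under Wnt-C59 1 rose, 6 fell and 5 did not pass (1 up and 7 down adjusted over the list alone, camera adjusted p = 0.11) and under the combination 1 rose, 3 fell and 8 did not pass (camera adjusted p = 0.82). Against syngeneic skin, macrophage markers numbered 15, of which under Wnt-C59 8 rose and 7 did not pass (camera adjusted p = 0.012, adjusted p = 0.59 with an estimated correlation) and under the combination 11 rose and 4 did not pass (14 up and 0 down adjusted over the list alone, camera adjusted p = 0.00042, adjusted p = 0.5 with an estimated correlation). MHC class II genes numbered 11, of which under Wnt-C59 10 rose and 1 did not pass (camera adjusted p = 7e-04, adjusted p = 0.55 with an estimated correlation) and under the combination 10 rose and 1 did not pass (camera adjusted p = 0.00017, adjusted p = 0.47 with an estimated correlation). Collagens and matrix genes numbered 36, of which under Wnt-C59 9 rose, 6 fell and 21 did not pass (6 up and 6 down adjusted over the list alone, camera adjusted p = 0.99) and under the combination 17 rose, 4 fell and 15 did not pass (camera adjusted p = 0.059).

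A score of 9 follicle markers outside hair growth was 6.61 ± 0.15 in syngeneic (SD, n = 4), 3.79 ± 0.44 in allogeneic (n = 3), 6.99 ± 0.26 in Wnt-C59 (n = 4) and 6.91 ± 0.24 in combination libraries (n = 4), values not compared by a test. Krt79, a keratin of the upper follicle and sebaceous ducts chosen after its values were seen, lay at 899 to 1490 CPM in syngeneic, 38.1 to 259 CPM in allogeneic and 1700 to 3260 CPM in treated libraries. Of other genes chosen after their values were seen, Alb was at 1180, Apoa1 at 108 and Ttr at 76.6 CPM in Wnt-C59 library 4, and Alb was at 0.718 to 19.4 CPM in the other treated libraries. The skeletal actin Acta1 was at 4.12 CPM in combination library 5 and at 1000 to 13200 CPM in the other combination libraries. Pgam1-ps2, a pseudogene, had 0 counts in every vehicle library and 33.9 to 85.3 CPM in treated libraries. Xist was at 500 to 1620 CPM in vehicle and at 90.9 to 198 CPM in treated libraries.

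The libraries of each comparison were split in 35 ways into groups of the real sizes, the real split included. Only the real split called as many genes in each of the 6 comparisons, the smallest share possible. This argues against chance except where stated. The real split called 5556 genes between allogeneic and syngeneic skin and the highest other split 1566. Against allogeneic skin it called 9481 for Wnt-C59 and 10168 for the combination, with 5388 and 5423 as the highest others. For the combination against Wnt-C59 it called 43 and the highest other 0, but the 43 fell to 1, 3, 3 and 5 without certain single libraries, so chance stays open there. Against syngeneic skin it called 9898 for Wnt-C59 and 10081 for the combination, with 0 and 1464 as the highest others. Between treated and vehicle skin these splits cannot tell treatment from a batch.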
